A study of Mus musculus with 8 samples.

How the data were processed

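Total RNA was extracted with Trizol from mouse primary keratinocytes carrying an empty retrovirus, and biotinylated cRNA was hybridised to Affymetrix arrays, per the labels. The 8 arrays comprise 2 untreated arrays and 1 array at each of 20, 40, 60, 120, 180 and 240 min after tamoxifen. Groups were taken from the sample titles. A general description shared by all samples speaks of tamoxifen treatment, including for the 2 arrays titled untreated, and the titles were followed. The labels give no batch, and they do not say whether the arrays came from separate cultures, so p-values measure only the spread between these arrays. That spread may be technical and, where times are pooled, it also holds the differences between times.

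The deposited values are linear intensities for 22690 probe sets. The method by which the authors summarised probes and scaled the arrays is not given in the sources used here. Intensities ranged over similar values in each array, with medians between 192 and 198 and highest values between 20138 and 20474. Medians of the log2 values lay within 0.04 of each other, so the values were used as deposited, without further scaling, as log2(intensity + 16). Log2 differences and folds are on that scale, which understates the change of dim probe sets. The number of arrays limits the precision.

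Genes were named from the platform annotation supplied with the array, whose symbols were compared with RefSeq genes of assembly GRCm38.p6 through Entrez identifiers. Leaving out 64 control probe sets, 20380 probe sets had 1 gene symbol, 691 had several and 1555 are unnamed here. Of the first, 20364 matched RefSeq and none of the symbols differed. Builds are not named in the files, so no coordinates are given. The 30% of probe sets with the lowest mean were left out (mean log2 below 7.04). Each gene was represented by the probe set with the highest mean among those with a single symbol, which left 9294 genes.

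Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Because each tamoxifen time has 1 array, times were pooled. The arrays of a pooled group are different times, not replicates, and the spread within it includes the differences between times. One fit compared all 6 tamoxifen arrays with the untreated arrays. A second fit had 3 windows (untreated, 20 to 60 min and 120 to 240 min, with 2, 3 and 3 arrays and 5 residual degrees of freedom) and gave 3 contrasts. Another fit tested a natural spline with 3 degrees of freedom over the sampling order. Genes at least 2-fold from both untreated arrays in the same direction were counted at each time, with no test. The comparisons of the 2 windows with untreated share the same 2 untreated arrays. There were 39 gene lists, for keratinocyte states, cell junctions, responses to stimuli and stress, signalling, cell cycle, housekeeping and other cell types. Those of T cells and erythroid cells had 3 genes each and were not tested. The 37 with at least 5 genes tested were compared with all other genes by camera (preset correlation 0.01, adjusted over the lists of each contrast), again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and does not compare the list with other genes.

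The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names up to 10 genes in each direction that pass, or the 5 with the smallest unadjusted p where none pass. It also names up to 4 members of each list described, the 5 largest differences in each direction per time, and a fixed set of early-response, sterol, keratin, estrogen and xenobiotic response and reference genes. Insig1 and Gapdh belong to that set but have no probe set with a single symbol here and were not analysed here. Some members of the set are not reported here.

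The tests were tried on simulated arrays with independent noise, drawn from the variances limma fitted, in which 200 of 9294 genes were changed. For a 1.41-fold change the tests recovered 87.6% of changed genes for all tamoxifen arrays, 85.9% for 20 to 60 min, 87.2% for 120 to 240 min and 93.4% between the windows. For a 2-fold change, each of these recovered at least 99.1%. In these simulations a changed gene was shifted by the same amount in every array of the pooled group. The shares therefore do not hold for genes whose change differs between the pooled times. In the data, Adm differed by 1.02 (log2) at 20 to 60 min and did not pass. The spline test recovered 13.7% of genes with a steady 1.41-fold trend and 55.6% with a smooth 1.41-fold rise and return. At 2-fold it recovered 96.0% and 95.9%. It recovered 0% of genes changed at 40 and 60 min alone, even at 4-fold. The spline had been chosen to catch rises at 1 or 2 times, and the simulation shows that it does not catch an abrupt one. Noise shared between genes was not simulated.

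Alternatives were other pseudocounts (1 and 64), quantile normalization, median centring, no filter or leaving out the dimmest 50%, all probe sets, other variance priors, array weights, leaving out each array, other curves and other fold limits. Fits with the mean of the G2 and M phase list or of the S phase list in each array as a covariate were added after seeing the data.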

Results

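The series followed gene expression in mouse primary keratinocytes, the main cells of the epidermis, over 4 hours after tamoxifen, a ligand of the estrogen receptor that is also used to activate proteins fused to that receptor's ligand-binding domain. The cells carried an empty retrovirus, so the arrays record what tamoxifen and handling do in the absence of an introduced gene. There were 2 untreated arrays and 6 tamoxifen arrays, 1 at each of 20, 40, 60, 120, 180 and 240 min. No tamoxifen time has a replicate, and no array of cells handled without tamoxifen at the same times was analysed here.

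The 2 untreated arrays differed from each other in genes of the cell cycle. The mean of 31 G2 and M phase genes was 9.56 (log2) in untreated replicate 1 and 8.80 in untreated replicate 2, a difference of -0.76, and the mean of 27 S phase genes differed by -0.36. Of the 6 genes at least 2-fold apart between the untreated arrays, Tk1, a thymidine kinase made in S phase, Ccna2, a cyclin, Aspm and Plk1, which act in mitosis, and Mki67, a marker of proliferating cells, were lower in replicate 2, with log2 differences of -1.14, -1.10, -1.02, -1.07 and -1.05. Susd4 was higher there by 1.83. The tamoxifen arrays spanned much of the same range, with G2 and M phase means of 9.04, 9.35, 9.25, 8.81, 8.90 and 9.47 from 20 to 240 min. The first principal component held 61.2% of the variance and placed untreated replicate 2 at 9.49 with the 120 min (11.67) and 180 min (6.93) arrays. Untreated replicate 1 lay at -1.76, and the 20, 40, 60 and 240 min arrays at -2.72, -8.51, -10.52 and -4.58. Across genes, which are not independent replicates, Pearson's r between the untreated arrays was 0.994, and between untreated replicate 1 and the 240 min array 0.997.

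**Figure D1:**
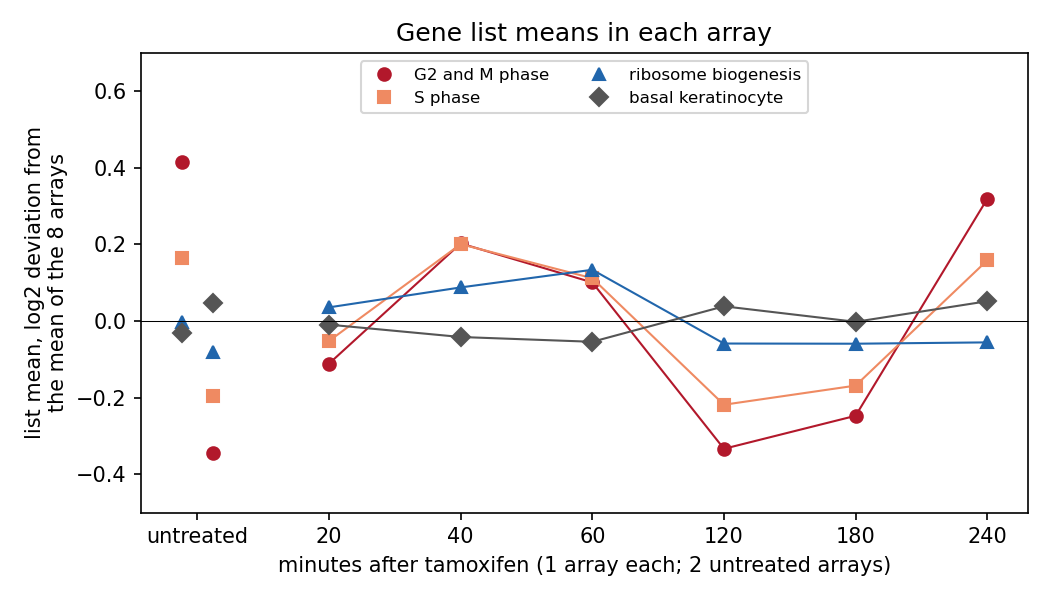
Mean of 4 gene lists in each array, as the log2 deviation from the mean of the 8 arrays, against sampling time in minutes (times equally spaced; points are single arrays, lines join the tamoxifen arrays, and both untreated arrays stand at the left, replicate 1 first). The G2 and M phase mean was 0.41 and -0.35 in the 2 untreated arrays, while the ribosome biogenesis mean lay at 0.04, 0.09 and 0.13 at 20, 40 and 60 min and at -0.06 at each later time. Between the untreated arrays the ribosome biogenesis mean differed by -0.08 (replicate 2 minus replicate 1).

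The comparison of all 6 tamoxifen arrays with the untreated arrays asks what is shared by all times. No gene of 9294 passed in limma, the smallest adjusted p was 0.974, and 320 genes had an unadjusted p under 0.05 where 464.7 would be expected by chance (143 without untreated replicate 2 and 614 without the 120 min array). The count expected by chance is an average, and where genes vary together a single count can lie far from it. Among values that did not pass, the genes with the smallest p above untreated were Mavs (log2 difference 0.25 ± 0.05, SE), Id2 (0.22 ± 0.06), Dnaja3 (0.17 ± 0.05), Dlx2 (0.18 ± 0.05) and Otud7b (0.19 ± 0.05). Those below untreated were Mmp3, a matrix protease (-0.25 ± 0.05), Zdhhc2 (-0.27 ± 0.05), Acsm2 (-0.20 ± 0.04), the chemokine Ccl20 (-0.20 ± 0.04) and Ptprd (-0.49 ± 0.11). Other probe sets departed from several of these values. Those of Dnaja3 were at 0.08 and -0.00744 at 20 to 60 min and -0.01 and 0.02 at 120 to 240 min, and that of Mavs was at 0.14 and 0.08. Those of Zdhhc2 were at 0.05 and 0.11 at 20 to 60 min and those of Ptprd at -0.03 and 0.05, all below the brightness filter.

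At 20 to 60 min, Adm, which encodes the peptide adrenomedullin, had a mean of 9.26 ± 0.35 (SD over 3 times, 1 array each). The untreated mean was 8.24 ± 0.15 (SD, n = 2). The Adm difference, 1.02 ± 0.17 (log2, SE), was among those farthest from untreated by p, as was that of the chemokine Cxcl1 at -0.62 ± 0.12. Neither passed: no gene did in limma, with a smallest adjusted p of 0.331, while 1288 genes had an unadjusted p under 0.05, 620 of them higher and 668 lower. That count was 342 without untreated replicate 2, under the 464.7 expected by chance, 730 without 60 min and 823 without 40 min. Of 2 covariates chosen after seeing the data, the G2 and M phase mean of each array gave 598 genes, Adm among them (1.01, adjusted p = 0.0140), and the S phase mean gave 0 (smallest adjusted p 0.0555). Other values with the smallest p were those of Stbd1 (0.56 ± 0.09), 2810004N23Rik (0.30 ± 0.06), the growth arrest gene Gadd45a (0.44 ± 0.09) and the amino acid transporter Slc7a3 (0.25 ± 0.05) above untreated. Fam162a (-0.59 ± 0.11), Nrep (-0.31 ± 0.06), Dnajb4 (-0.28 ± 0.05) and Acsm2 (-0.23 ± 0.05) lay below. Other probe sets gave -0.08 for Nrep, -0.16 for Dnajb4 and, all below the brightness filter, -0.06, -0.06 and 7.72e-04 for Acsm2.

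Of 28 ribosome biogenesis genes, 26 were higher at 20 to 60 min than in untreated arrays and 2 lower, with a mean log2 difference of 0.13 (camera, adjusted p = 2.30e-09 with the preset correlation). Nop58 and Nop56, core proteins of nucleolar RNA-protein particles, were at 0.27 ± 0.06 and 0.23 ± 0.07 (SE), Pes1 at 0.20 ± 0.05 and Wdr43 at 0.24 ± 0.08. Of 26 genes of cell junctions and the actin cytoskeleton, 24 were higher, with a mean of 0.12 (adjusted p = 9.92e-05), among them Zyx, a focal adhesion protein (0.46 ± 0.14), the tight junction gene Cldn4 (0.28 ± 0.09), Flna (0.21 ± 0.07) and Cnn2 (0.23 ± 0.08). Of 20 NF-kB and inflammatory genes, 16 were lower, with a mean of -0.15 (adjusted p = 0.00188). Examples besides Cxcl1 were Tnf (-0.25 ± 0.05), Ccl20 (-0.21 ± 0.05) and Nfkbia, which encodes an inhibitor of NF-kB (-0.28 ± 0.07). All 10 leukocyte and Langerhans cell genes were lower, with a mean of -0.13 (adjusted p = 0.0144), including the MHC class II genes H2-Ab1 (-0.35 ± 0.14) and H2-Eb1 (-0.20 ± 0.07). Without untreated replicate 2, the adjusted p of that last list was 0.0876. The untreated arrays themselves differed (replicate 2 minus replicate 1) by -0.08 on the ribosome biogenesis list and -0.05 on the junction list. They differed by 0.04 on the NF-kB list and 0.11 on the leukocyte list. None of these 4 lists passed with an estimated correlation between genes: the adjusted p was 0.924 for ribosome biogenesis and for NF-kB and 0.970 for the junction and leukocyte lists. No member passed over all genes, and adjusted over the list alone 2 ribosome biogenesis genes, 5 NF-kB genes and 0 of the junction and leukocyte genes passed. A further probe set of Pes1, below the brightness filter, gave 0.03, and those of H2-Ab1 gave -0.28 and -0.13. In the same window the mean of 5 adipocyte genes was -0.20 (adjusted p = 0.707), with Fabp4, a fatty acid binding protein, at -0.95 ± 0.37 (SE). Fabp4 was 9.79 and 10.63 in the 2 untreated arrays.

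Genes of the unfolded protein and amino acid stress list lay on both sides of 0 at 20 to 60 min and gave no call (adjusted p = 0.560). Its mean was 0.08 and its median -0.03, with 9 members above 0 and 13 below. Its members with the smallest p were the stress transcription factor gene Ddit3 (0.52 ± 0.12, SE), Chac1, which degrades glutathione (0.65 ± 0.17), the stress-induced pseudokinase gene Trib3 (0.82 ± 0.22) and the serine synthesis gene Phgdh (0.18 ± 0.05). Adjusted over the list alone, 8 of its 22 genes passed, and 10 did between the windows, where its mean was -0.06 (adjusted p = 0.721). A further probe set of Trib3 gave 0.76.

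At 120 to 240 min, Npn2 was the gene farthest from untreated by p. Its log2 values were 7.65, 7.89 and 7.69 at 120, 180 and 240 min, against 6.97 and 6.90 in the untreated arrays and 6.91, 7.15 and 7.01 at 20, 40 and 60 min. The difference from untreated was 0.81 ± 0.09 (SE) and missed the threshold (limma, adjusted p = 0.0567). Both untreated values lay below the limit of the brightness filter, 7.04, and the difference lay between 0.62 and 0.93 over the alternatives, which include other pseudocounts. Its adjusted p lay between 0.0151, with array weights, and 0.955, without untreated replicate 2, over the alternatives fixed beforehand, and was under the threshold in 4 of them. The other probe set of Npn2 differed by -0.03, so the 2 probe sets disagree. No gene passed, and 295 had an unadjusted p under 0.05, against 464.7 expected by chance (177 without 180 min and 522 without 240 min). The next smallest p above untreated were those of Mavs (0.29 ± 0.05), C9orf72 (0.25 ± 0.06), Pmepa1, a target of TGF-beta (0.24 ± 0.06), and Fam222b (0.17 ± 0.05). Cd209c (-0.28 ± 0.05), Zdhhc2 (-0.28 ± 0.06), Mocos (-0.29 ± 0.07), Mmp3 (-0.25 ± 0.06) and Ptprd (-0.53 ± 0.12) lay below. Other probe sets departed from some of these values: 0.08 for Mavs, 0.02 for Fam222b, 0.20 and 0.09 for Pmepa1 and, all below the brightness filter, 0.01 and 0.05 for Zdhhc2 and 0.08 and 0.13 for Ptprd.

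Of the NF-kB and inflammatory genes, 17 of 20 were lower at 120 to 240 min than in the same untreated arrays, with a mean of -0.09 (camera, adjusted p = 1.59e-04; adjusted p = 0.598 with an estimated correlation). Ccl20 was at -0.18 ± 0.05 (SE) and Cxcl1 at -0.25 ± 0.12. Of 10 leukocyte and Langerhans cell genes, 8 were lower too, with a mean of -0.04, and that list gave no call (camera, adjusted p = 0.121). All 31 G2 and M phase genes were lower, with a mean of -0.12 (adjusted p = 0.0370; adjusted p = 0.918 with an estimated correlation). That mean is smaller than the -0.76 between the 2 untreated arrays, and its direction rests on the untreated arrays: without untreated replicate 1 the list was called higher (adjusted p = 3.33e-07), and without untreated replicate 2 it was called lower (adjusted p = 2.45e-24). The call ended without the 120 min array (adjusted p = 0.973), without 180 min (0.552), without 60 min (0.0704), with no filter (0.0823) and with the S phase covariate (0.594). Adjusted over the list alone, 0 genes of the NF-kB list or of the G2 and M phase list passed. Between the windows the NF-kB mean was 0.07 (adjusted p = 0.532), and 6 of its genes passed when adjusted over the list alone.

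Between the 2 windows, Adm was lower at 120 to 240 min than at 20 to 60 min by a log2 difference of -1.09 ± 0.15 (SE; limma, adjusted p = 0.158), and Npn2 was higher by 0.72 ± 0.08 (adjusted p = 0.0617). Neither passed and no other gene did, although 1811 had an unadjusted p under 0.05, 1119 of them higher and 692 lower. That count was 877 without the 120 min array, 975 without 180 min, 1011 without 40 min and 2884 without 240 min. Other values with the smallest p were those of Fzd6, a Wnt receptor (0.36 ± 0.05), Dnajb4 (0.31 ± 0.05), Pmepa1 (0.33 ± 0.06) and C1qtnf12 (0.48 ± 0.08) on the higher side. On the lower side were Slc7a3 (-0.29 ± 0.05), 2810004N23Rik (-0.30 ± 0.05), Cyb5r1 (-0.42 ± 0.07) and Erf (-0.29 ± 0.05). Other probe sets gave 0.17 for Fzd6, 0.31 for Dnajb4, 0.17 and 0.24 for Pmepa1, 0.44, 0.41 and 0.00757 for C1qtnf12 and -0.07 for Erf. With array weights 2859 genes passed, without the 240 min array 1024 did, with the G2 and M phase covariate 537 did and with the S phase covariate 1 did.

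Ribosome biogenesis genes were lower at 120 to 240 min than at 20 to 60 min in 27 of 28 cases, with a mean of -0.14 (camera, adjusted p = 2.01e-11), among them Nop56 (-0.32 ± 0.06, SE), Nop58 (-0.25 ± 0.05), Gnl3 (-0.21 ± 0.05) and Rrs1 (-0.19 ± 0.04). Of 27 S phase genes 23 were lower, with a mean of -0.16 (adjusted p = 0.00106), among them Ung (-0.28 ± 0.09), a uracil glycosylase, and Cdt1 (-0.36 ± 0.14), a replication licensing factor. Of 31 G2 and M phase genes 28 were lower, with a mean of -0.15 (adjusted p = 0.0453), among them Ccna2 (-0.47 ± 0.32) and Mki67 (-0.33 ± 0.32). Of 26 junction and actin genes 20 were lower, with a mean of -0.08 (adjusted p = 0.00823), among them Zyx (-0.40 ± 0.13) and Actn1 (-0.14 ± 0.05). With an estimated correlation none of the 4 lists passed (adjusted p = 0.994 for each), and that correlation was 0.96 for G2 and M phase, 0.80 for S phase, 0.34 for junctions and 0.27 for ribosome biogenesis. Adjusted over the list alone, 10 ribosome biogenesis genes passed and 0 of the other lists. Without the 120 min array the adjusted p was 0.132 for S phase, 0.156 for junctions and 0.502 for G2 and M phase. The S phase call also ended without 40 min (0.102), the junction call without 60 min (0.101), and the G2 and M phase call without 40 (0.537), 60 (0.0778) or 180 min (0.327). The G2 and M phase call ended too after quantile normalization (0.104), median centring (0.104) or leaving out the dimmest 50% (0.0985). With the S phase covariate the G2 and M phase list was called higher (adjusted p = 3.73e-08), and the junction call ended (0.0846). Among markers of other cells, whose lists did not pass, 12 of 14 fibroblast genes were higher, with a mean of 0.09 (adjusted p = 0.115), among them Col6a1 (0.22 ± 0.06), Col1a2 (0.18 ± 0.05) and Sparc (0.25 ± 0.09). The leukocyte and Langerhans cell mean was 0.09 (7 of 10 higher, adjusted p = 0.450) and the muscle mean 0.09 (5 of 6 higher, adjusted p = 0.754). The melanocyte mean was 0.02 and the endothelial mean -0.01. The adipocyte mean was 0.16 (adjusted p = 0.943), with Fabp4 at 0.92 ± 0.33.

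Over the time course, no gene passed the spline test (limma, smallest adjusted p 0.629) and 576 had an unadjusted p under 0.05. That count was 2027 without untreated replicate 1, 1527 without 60 min, 307 without 120 min, 210 without 40 min and 157 without 180 min. Other curves gave no passing gene either: a spline over minutes gave 2338 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0526, a spline with 2 degrees of freedom 267 genes and 1.00, and a linear trend over minutes 216 genes and 0.888. The genes with the smallest p had their largest difference from the untreated mean above it for Chtf8 (0.58), Tsr1 (0.23), Gadd45a (0.56), Ccl11 (0.35) and Npn2 (0.96), and below it for Bnipl (-0.46), Nrep (-0.38), Ajuba (-0.88), Id1 (-0.28) and Cd209c (-0.36). In simulated arrays the test recovered 0% of genes changed at 40 and 60 min alone and 13.7% of those with a steady 1.41-fold trend. It therefore does not exclude such changes.

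At single times, 3 genes were at least 2-fold from both untreated arrays, all at 60 min, with no replicate to check them. Adm was 1.30 and 1.51 above the 2 untreated arrays (log2), Stfa3, a cysteine protease inhibitor, was at -1.05 and -1.17, and Ccnb1ip1 at -1.04 and -1.18. At 20, 40, 120, 180 and 240 min the count was 0. Between the 2 untreated arrays 6 genes were 2-fold apart, a count over 1 pair of arrays. Counted over 1 pair likewise, from 20 to 240 min, it was 0, 0, 4, 6, 2 and 0 from untreated replicate 1. From untreated replicate 2 it was 2, 9, 24, 1, 1 and 6. The 60 min array also had the lowest 3' minus 5' log2 difference of Actb, 0.20, against 0.26 to 0.28 in the other arrays. Whether this bears on the counts was not tested. Differences from the untreated mean that came closest included Adm at 20 min (0.73) and 40 min (0.92), Trib3 (0.87) and Max (-1.16) at 40 min, Ccn2 (1.02), Znrd1 (1.11), Edn1, which encodes endothelin 1 (0.92), Ifitm3 (-1.03) and Tnfrsf18 (-0.94) at 60 min. Later they included Rpl27a (-0.88) at 120 min, Npn2 (0.96) at 180 min, and Ajuba (-0.88) and Rad1 (-0.90) at 240 min. Among rises ranked by the nearer untreated array, Xist came next after Adm at 20 min (0.47 from the untreated mean). It came next after Npn2 at 240 min (0.66).

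**Figure D2:**
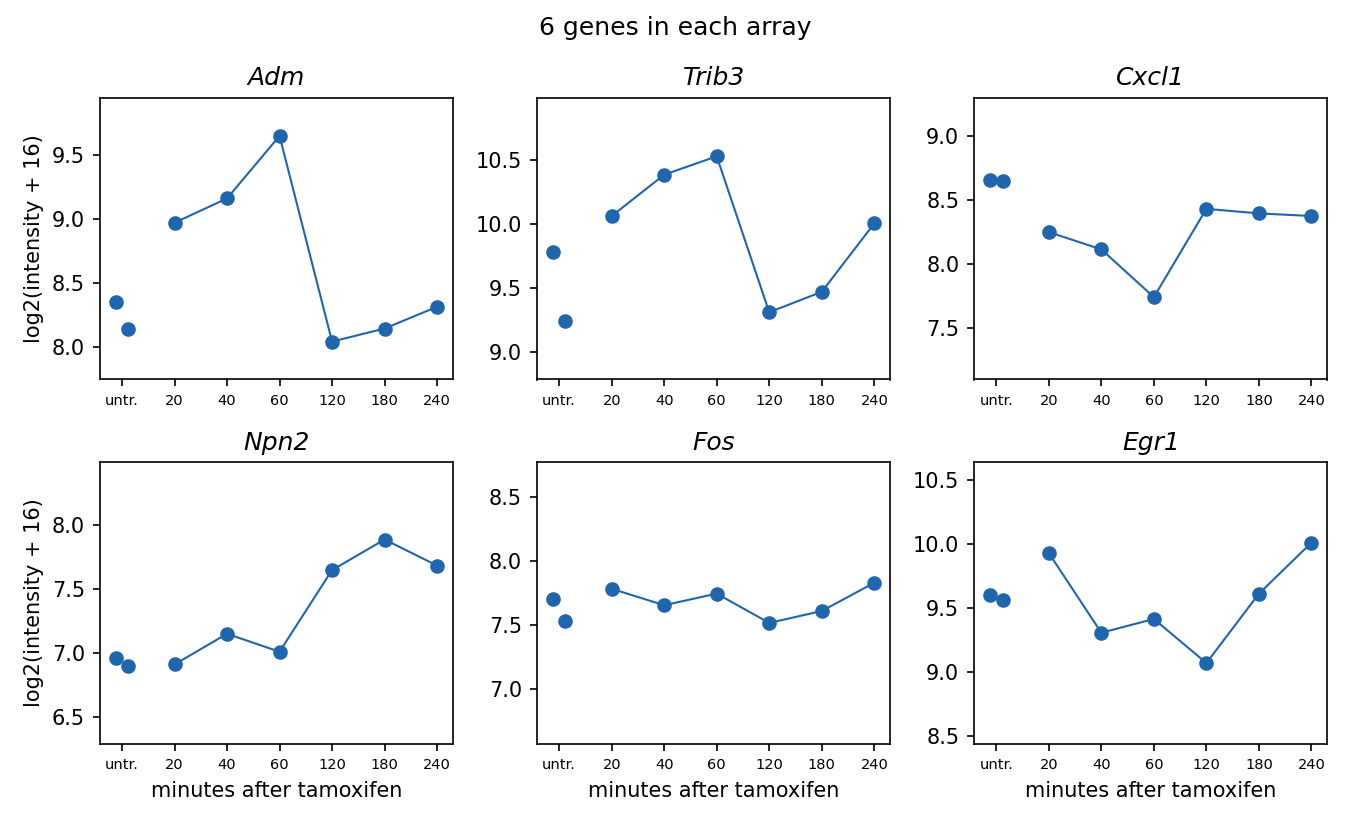
Log2(intensity + 16) of 6 genes in each array against minutes after tamoxifen (times equally spaced; each point is 1 array, the line joins the tamoxifen arrays, the untreated arrays stand at the left, replicate 1 first, and each vertical axis spans the same log2 range). Adm went from 8.97 at 20 min to 9.65 at 60 min and was 8.04 at 120 min, Npn2 lay at 7.65 or above from 120 min, and Fos lay between 7.52 and 7.83 in the 8 arrays.

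Genes that respond early to growth signals gave no list call. Of 35 immediate early genes, 20 were above and 15 below untreated at 20 to 60 min, with a mean of 0.04 (adjusted p = 0.242), and at 120 to 240 min the mean was 0.00439 (adjusted p = 0.941). Between the windows the mean was -0.04 (adjusted p = 0.245), with Egr2 at -0.28 ± 0.06 (SE), Ptgs2 at -0.48 ± 0.11, Klf6 at -0.31 ± 0.07 and Btg2 at 0.28 ± 0.07. Adjusted over the list alone, 5 passed at 20 to 60 min, 0 at 120 to 240 min and 7 between the windows. Over the 8 arrays the log2 range was 0.31 for Fos, 0.25 for Ier2, 0.38 for Dusp1, 0.30 for Myc, 0.54 for Jun and 0.94 for Egr1. Egr1 was 9.60 and 9.56 untreated, 9.93 at 20 min, 9.07 at 120 min and 10.01 at 240 min. Jun was at 0.40 ± 0.09 (SE) and Ccn2, a matrix-associated signalling protein, at 0.67 ± 0.15 at 20 to 60 min (limma, adjusted p = 0.331 for each). A further probe set of Jun gave 0.20.

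Lists for estrogen receptor, xenobiotic and sterol responses gave no call either. Of 13 estrogen receptor targets, 5 were above and 8 below untreated in both windows, with means of 0.00915 (adjusted p = 0.995) and -0.01 (adjusted p = 0.611). The 11 xenobiotic response genes had means of -0.09 (adjusted p = 0.199) and 0.03 (adjusted p = 0.723), and the 20 genes of cholesterol synthesis means of -0.02 (adjusted p = 0.628) and -0.00740 (adjusted p = 0.693). Esr1 lay between 6.69 and 6.81, Pgr between 6.68 and 6.82 and Cyp1a1 between 6.79 and 6.95, all below the brightness filter at 7.04, where a lower level could not be followed. Cyp1b1 lay between 8.79 and 9.32, with both ends in the untreated arrays. Hmgcs1, an enzyme of sterol synthesis, ranged from 10.98 to 11.45 and was 11.31 and 10.98 in untreated replicates 1 and 2. On the cholesterol synthesis list the untreated arrays differed by -0.21 (replicate 2 minus replicate 1), against a range of 0.23 over the 8 arrays. The means of that list against untreated therefore average 2 unlike arrays, and do not show a steady level.

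The lists of basal, differentiated and wound-edge keratinocytes and of epithelial transcription factors gave no call in any of the 3 contrasts. The mean of 32 genes of stratified and terminal differentiation was -0.08 at 20 to 60 min (camera, adjusted p = 0.346), with 11 above 0 and 21 below. At 120 to 240 min it was -0.02 (adjusted p = 0.532). Adjusted over the list alone, 0 passed in either window against untreated and 3 between the windows. For the wound-edge list 1 passed in each window and 4 between them. At 20 min Lce1a1 lay at -0.72 and Lce1a2 at -0.61 from the untreated mean. Another probe set of Lce1a1 gave -0.69 at 20 to 60 min and 0.65 between the windows. Other probe sets of Lor gave -0.60 and -0.11, then 0.63 and 0.07. Krt5 ranged from 14.06 to 14.15 and Krt14 from 14.27 to 14.32, which is at the top of the arrays' scale, so the narrow range does not show a steady level. Krt1 ranged from 10.70 to 11.43, Krt10 from 9.53 to 10.01 and Ivl, a cornified envelope gene, from 8.59 to 9.14. Actb ranged from 13.89 to 13.96, also near the top of the scale, and its dimmer probe set was at -0.16 at 20 to 60 min and -0.31 at 120 to 240 min. Against untreated, the fibroblast mean was -0.06 at 20 to 60 min (adjusted p = 0.321) and 0.03 at 120 to 240 min (adjusted p = 0.532), and the melanocyte mean 0.03 (adjusted p = 0.474) and 0.05 (adjusted p = 0.230). The adipocyte mean, over 5 genes, was 0.22 higher in untreated replicate 2 than in replicate 1.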

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

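The tests of scaling, of RNA quality, of the share of keratinocytes, of cell cycle covariates and of the other Npn2 probe set were chosen after the results they concern had been seen.

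The shift of 4 gene lists differed between the 2 windows by the test of that difference with a preset correlation: ribosome biogenesis (-0.14), S phase (-0.16), G2 and M phase (-0.15) and cell junctions and actin cytoskeleton (-0.077), each as the mean log2 difference of 120 to 240 min minus 20 to 60 min. With an estimated correlation none of the 4 passed (adjusted p = 0.994 for each). Of the 10 splits of the 6 tamoxifen arrays into 3 and 3, 6 called at least as many lists as the real one, the real one included. The real one called 4, and the highest of the others called 9. With 10 splits no share under 0.05 can be reached. For genes past the adjusted threshold the real count was 0 and the highest other 0; all 10 splits match a count of 0 by construction, so that comparison says nothing about chance. At an unadjusted p under 0.05 the real split gave 1811 genes and the split of 20, 120 and 180 min against the rest gave 1973, so the arrays hold a structure that the windows do not follow.

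Among 13332 probe sets outside the tests, 3 were at least 2-fold from both untreated arrays at a single time, against 2 that were 2-fold apart between the untreated arrays. A dim probe set of Ptpn2 was 2.16 (log2) above the untreated mean at 60 min, a second probe set of Cd151 was 1.20 above at 120 min, and an unnamed probe set was 1.21 above at 180 min.

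The untreated arrays stood apart in cell cycle genes, by -0.76 over 31 G2 and M phase genes. After quantile normalization the difference was -0.76 ± 0.03 (SE over genes). The medians of the log2 values already lay within 0.04 of each other, so that step had little to change. It cannot decide about the scaling done before deposit. The 3' minus 5' difference of Actb or Gapdh differed between these arrays by at most 0.020, less than the range of 0.068 over the tamoxifen arrays. Actb lay near the top of the scale, where such a difference can be flattened. The Gapdh value was below 0 in every array (-0.068 to -5.81e-04). These values therefore cannot decide about RNA quality. The basal keratinocyte list was higher by 0.078 ± 0.020 (SE over genes of 1 pair of arrays). Adipocyte (0.22), leukocyte (0.11), muscle (0.10) and fibroblast (0.05) markers were higher there too, with melanocyte markers at -0.02. Because markers of several other cells rose as well, these values cannot decide about the share of keratinocytes. No group in the design separates the 2 arrays, so no biological explanation was tested, and a difference in the share of dividing cells between cultures stays open.

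Ribosome biogenesis genes were lower at 120 to 240 min than at 20 to 60 min by -0.14. The mean difference was -0.13 ± 0.03 (SE) with the G2 and M phase mean in the fit and -0.12 ± 0.03 with the S phase mean. These values argue against either cell cycle difference as the whole cause. After quantile normalization the mean difference was -0.15 ± 0.03, but that step had little to change here and cannot decide about scaling. The real split was 1 of 10 with a mean as far from 0, the highest other being 0.08, and 10 splits cannot give a share under 0.05. Time after tamoxifen, which the design names, and the handling that goes with it stay open and cannot be separated without arrays of cells handled without tamoxifen.

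Npn2 was higher at 120 to 240 min by 0.81. With the G2 and M phase mean in the fit the difference was 0.82 ± 0.08 (SE), against the cell cycle difference as its cause. The 56 splits of the 8 arrays into 3 and 5 were counted after the gene had been seen to be high at those times. Of these, 2 had a gene with as small a p, the real one included. Each split sets 3 arrays against the other 5, so its p is not that of the difference from untreated. The probe set also passed the filter, and was chosen for the gene, by a mean that includes its high values. The count therefore cannot decide about chance. The smallest p was 1.28e-06 in the real split (unadjusted, moderated test) and 1.47e-07 in the split that set untreated replicate 2 with 120 and 180 min apart. The other probe set of the gene differed by -0.031 ± 0.068, so a signal that 1 probe set alone reads, such as a transcript variant or cross-hybridisation, may account for it.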

How the results depend on the processing

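The fits with a cell cycle covariate were chosen after the results were seen. All other alternatives were fixed before the data were examined. No paired analysis was possible because each tamoxifen time has 1 array and the labels give no replicate numbers shared between groups. Where leaving out an untreated array leaves 1, that array is assumed to vary like the other windows. The cause of these shifts was not tested, except that leaving out an array also lowers the number of arrays.

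Genes that passed for 120 to 240 min against untreated numbered 1 with a pseudocount of 1, with a prior with a trend, with a robust prior, with array weights, with the G2 and M phase covariate and with the S phase covariate, and that gene was Npn2 each time. Between the windows, 1 passed with a prior with a trend, 1 with a robust prior and 2859 with array weights, which ran from 0.378 to 7.12. There 537 passed with the G2 and M phase covariate and 1 with the S phase covariate. At 20 to 60 min 598 passed with the G2 and M phase covariate and 0 with the S phase covariate. Over the time course 6979 passed with array weights, a fit whose weights, from 0.167 to 29.7, did not converge. Leaving out each array in turn gave 0 to 1 genes for all tamoxifen arrays, 0 to 2 for 20 to 60 min, 0 to 1 for 120 to 240 min and 0 to 1024 between the windows. The 1024 came without the 240 min array, the 2 (Lce1a1 and Lce1a2) without the 120 min array, and the 1 in each comparison with untreated was Susd4, without untreated replicate 1.

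Gene lists called at 20 to 60 min numbered 0 with an estimated correlation, 0 with fry and 4 to 9 with each array left out (7 without untreated replicate 1 and 9 without untreated replicate 2). At 120 to 240 min they numbered 4 with median centring, 1 with no filter, 6 with the dimmest 50% left out, 1 with the G2 and M phase covariate, which takes out that list's own difference by construction, 1 with the S phase covariate, 0 with an estimated correlation, 0 with fry and 1 to 7 with each array left out (5 and 7 without untreated replicates 1 and 2, 1 without 60 min, 4 without 120 min and 6 without 240 min). Between the windows they numbered 0 with an estimated correlation, 0 with fry and 1 to 6 with each array left out (2 without 40 min, 2 without 60 min and 1 without 120 min). Ribosome biogenesis, at 20 to 60 min and between the windows, and the NF-kB list, in both windows, were called in all 14 alternatives fixed beforehand that use camera with the preset correlation. The G2 and M phase list was called lower in 9 of these 14 and higher in 1, without untreated replicate 1, at 120 to 240 min, and lower in 7 of 14 between the windows.

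Genes 2-fold from the untreated mean numbered 1 at 20 min, 2 at 40 min and 11 at 60 min. Genes 1.5-fold from both untreated arrays numbered 3, 7, 44, 2, 1 and 5 from 20 to 240 min, and a pseudocount of 1 gave 1 gene at 180 min. With each untreated array left out the counts were 0 to 2 at 20 min, 0 to 9 at 40 min, 4 to 24 at 60 min, 1 to 6 at 120 min, 1 to 2 at 180 min and 0 to 6 at 240 min.

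Of the 117 pairs of a named gene and a comparison, none was past the threshold as reported. Alternatives fixed beforehand put 57 values past it, 10 of them in the time course with the array weights that did not converge. Others of the 57 came with the uneven array weights of the 3 windows, such as that of Adm between the windows. The alternatives left 1994 values on the same side with the same sign and turned the sign of 41. Signal near the floor limits dim genes, such as Npn2, which the filter leaving out the dimmest 50% removes.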

Other observations

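The tests in this part were fixed before the data were examined. Some further lists missed the threshold of camera and are given as values. Of 11 xenobiotic response genes, 10 were higher at 120 to 240 min than at 20 to 60 min, with a mean log2 difference of 0.12 (adjusted p = 0.0915; adjusted p = 0.994 with an estimated correlation). Against untreated the mean was -0.09 at 20 to 60 min and 0.03 at 120 to 240 min, so most of the difference lay in lower values at 20 to 60 min. Untreated replicate 2 was 0.09 above replicate 1 on this list. Adjusted over the list alone 3 passed. The members with the smallest p were Cyp2b10 (0.31 ± 0.06, SE), Ephx1, an epoxide hydrolase (0.22 ± 0.06), Gsta4, a glutathione transferase (0.32 ± 0.09), and Aldh3a1 (0.16 ± 0.07). Of 16 TGF-beta and BMP targets, 11 were higher at 120 to 240 min than in untreated arrays, with a mean of 0.06 (adjusted p = 0.0637; adjusted p = 0.598 with an estimated correlation), among them Pmepa1 (0.24 ± 0.06), Id2 (0.22 ± 0.06) and Skil (0.16 ± 0.05). Adjusted over the list alone 3 passed. No gene of either list passed over all genes.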
